A study of Mus musculus with 8 samples.

How the data were processed

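Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in group 3 innate lymphoid cells (ILC3s) from the small-intestinal lamina propria of mice aged 8 weeks. The labels state 50000 flow-sorted cells per library, paired-end reads of 150 nt, and biological duplicates for each of 4 groups, 8 libraries in all. Cells were sorted into NKp46- and NKp46+ ILC3s. Control mice (CTRL) carried floxed Setd2 alleles on a Rag1-deficient background, and knockout mice (KO) carried Rorc-cre in addition. Every KO library therefore carries cre and no CTRL library does. Replicate 1 of both genotypes in NKp46- cells is given as male and all other libraries as pools of males and females.

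Per the labels, the authors used FastQC, Bowtie2 and MACS2 with the mouse build mm10, with no versions stated. The deposited values are raw read counts per peak, with no normalization, in separate peak lists for the NKp46- and the NKp46+ libraries. How reads were counted and how duplicate and mitochondrial reads were handled is not stated. All value columns were assigned to a library, with 0 left over. Whole numbers that summed to a different total in each library were checked in every column. The coordinates are printed as the lists give them, and whether they start at 0 or 1 is not stated.

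The lists held 58850 peaks in NKp46- cells (median width 878 bp) and 54631 in NKp46+ cells (median width 1102 bp). Peaks were compared with 21887 protein-coding genes of a RefSeq annotation of the same build. That annotation gave no strand, so a peak within 1 kb of either end of a gene was classed as gene end in place of promoter, any other peak inside a gene as gene body, and the rest as intergenic. A peak at a gene end or inside a gene was assigned to that gene, however far inside it lay. An intergenic peak was assigned to the gene with the nearest end within 100 kb. Together this covered 93.2% of NKp46- and 94.6% of NKp46+ peaks. Counts were also summed over the peaks assigned to each gene, called gene-level counts here. Such an assignment says where a peak lies and not which gene it regulates. For comparisons across the subsets, 38037 pairs of peaks that each overlapped the other over at least 50% of their width were matched.

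KO and CTRL were compared within each subset with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on 4 libraries, with TMM scaling, filterByExpr (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment at 0.05. It is two-sided. The difference of the genotype effects and the subset contrast among CTRL libraries were tested in a fit of all 8 libraries on the matched peaks. CPM values are counts scaled by library total and TMM factor, given as mean ± SD over 2 libraries, and log2 fold changes are KO over CTRL with their standard error (SE). Description labels hold date-like codes that CTRL and KO libraries of the same number and subset share, so the numbers pair samples. For counts of calls, the genes always named and the lists, values with the replicate as a block are printed where they change a call or move a count by over 1.5 times. A blocked fit of 4 libraries leaves few residual degrees of freedom, so its p-values lean on variance shared across peaks or genes. NKp46- and NKp46+ libraries share no such code, so subset and what the codes mark cannot be told apart.

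The 23 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, on the gene-level counts, and adjusted over the 23 lists. They were ILC3 identity, CCR6+ (LTi-like) ILC3, NKp46+ ILC3 and type 1, ILC2 and type 2, effector cytokines, chemokine receptors and adhesion, AP-1 and activation, TGF-beta signaling, Notch signaling, AhR targets, MHC class II presentation, interferon response, cell cycle, apoptosis, glycolysis, H3K36 and related histone enzymes, lymphocyte inhibitory receptors, and markers of T cells, B and plasma cells, myeloid cells, mast cells and basophils, epithelial cells, and stromal and endothelial cells. The symbols Mx1, Mx2, Trac, Trbc1 and Trbc2 matched no gene in the annotation. Shares of peaks by location were compared with all tested peaks by a two-sided Fisher exact test, with 95% confidence intervals. Neighbouring peaks are not independent replicates.

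The comparisons, the lists, the tests and the rule for named genes were fixed before the data were examined. Setd2, Rorc, Ncr1, Tbx21, Il22, Il17a, Il17f, Ccr6 and Csf2 were always named. Beyond these, the rule took peaks past the threshold whose KO libraries both lay beyond both CTRL libraries, with a mean count of at least 20, on an autosome and assigned to a gene, 1 peak per gene by p. It named the 10 with the largest change in each direction per genotype comparison, 5 for the difference of effects and the subset contrast, and up to 4 members per list by p. Applying that rule to calls of the blocked fit in NKp46- cells and for the difference of effects was decided after their counts were seen.

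Alternatives tried were DESeq2 size factors, total counts and loess offsets as scaling, no count filter, a mean count of at least 20, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.5, an adjusted p of 0.1, the replicate block, all 8 libraries together, omission of chromosomes X and Y, omission of each library, peaks at gene ends only, gene ends of 3 kb, and matching by any overlap. The replicate block with loess offsets and with DESeq2 was added after the data were seen, and so were, for the subset contrast, pairs that overlap by at least 90% and counts per width of the interval. Peak overlaps used bedtools 2.31.1, and tables and plots used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Motif content and GC correction need the genome sequence, which was not used here, so neither was run.

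Counts in peaks ranged from 3186255 to 13223617 per library. Variation between replicates exceeded counting error: the chi-square per degree of freedom between replicates lay between 3.08 and 7.05. The biological coefficient of variation was 0.249 in NKp46- and 0.138 in NKp46+ cells, and 0.134 and 0.0884 with the replicate block. Deviations of CTRL and KO libraries of the same number from their group means correlated across peaks at 0.308 and 0.18. The tests were also run on simulated data with 200 changed peaks or genes. Each set was simulated from the means and dispersions of the fit it tested, so the shares with and without the block do not compare these fits on the same data. At a 4-fold change they found 46.2% of changed peaks in NKp46- cells, 78.5% with the block, and 90.9% in NKp46+ cells. At a 2-fold change these shares were 3.2%, 45.3% and 53.0%. For the difference of effects 42.4% were found at 4-fold and 4.5% at 2-fold. Of the 39 calls in that test, 8 were unchanged peaks. In NKp46- cells it was 1 of 34 calls, 1 of 91 with the block, and in NKp46+ cells 8 of 117. The blocked test of the difference was not simulated.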

Results

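Accessibility was profiled in NKp46- and NKp46+ ILC3s, cells that make IL-22 and IL-17 in the gut, from control mice and from mice in which Rorc-cre deletes Setd2, the enzyme that trimethylates histone H3 lysine 36. Each of the 4 groups had 2 libraries. Total counts in peaks were 8794719 and 4900138 in CTRL and 6277811 and 3186255 in KO NKp46- cells, and 13223617 and 6925628 in CTRL and 12365373 and 9554241 in KO NKp46+ cells. KO replicate 2 of the NKp46- cells stood apart from the other 3 libraries of its subset. It was the shallowest, and 4.26% of its counts lay in the weakest of 3 equal classes of peaks, against 2.32% to 2.43% in the others. Even so it had 1007 peaks without a count, fewer than the 1669 to 2792 of the others.

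The first comparison asked which regions change in accessibility in NKp46+ ILC3s without Setd2. Of 52419 peaks tested, 2156 were more open and 1719 less open in KO (3875 in all, edgeR). Of the 10 named gains, 9 lay inside or at the ends of genes. They included Hnrnpul1, which encodes an RNA-binding protein of the hnRNP family (log2 4.20 ± 0.28 SE, n = 2 per group, adjusted p = 3.6e-09, chromosome 7, 25746713 to 25749333), at 1.38 ± 0.12 CPM in CTRL and 25.1 ± 2.56 CPM in KO. Capn1, a calpain protease (4.49 ± 0.54, chromosome 19, 5988814 to 5989521), Gtf2a1, a subunit of TFIIA (4.21 ± 0.59), Jmjd1c, of the JmjC demethylase family (4.20 ± 0.47), Rad50, of double-strand break repair (3.76 ± 0.54), and Cnot10, a CCR4-NOT subunit (3.78 ± 0.56), also gained. Slc35f5, Washc4, Them5 and Otud7a completed the 10 named gains, with log2 changes between 3.69 and 4.34. In each of the 10, CTRL libraries lay at or below 2.04 CPM and both KO libraries at or above 3.02 CPM.

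The largest named loss was at Babam2, of the BRCA1-A repair complex (chromosome 5, 31921137 to 31922389), where CTRL libraries held 114 counts and KO libraries 1. That is a 124-fold lower count per depth, with an exact binomial 95% interval of 21.8 to 4940, which covers counting error only and not the larger variation between replicates. Agap1 followed at log2 -4.26 ± 0.72, then Ankrd23 at -4.06 ± 0.40 (12.75 ± 5.86 against 0.77 ± 0.05 CPM) and Ptpru, a receptor tyrosine phosphatase, at -3.58 ± 0.46. A peak 56403 bp from Irf8, which encodes an interferon regulatory factor of myeloid and lymphoid cells, fell by 3.51 ± 0.62, and BC053393 by 3.28 ± 0.36. Pla2g2d, Cpped1, Lnpep and Katnal1 had losses between -3.08 and -2.82. The peaks of Ptpru, Cpped1, Lnpep and Katnal1 also lay between genes, 17773 bp (Cpped1) to 96019 bp (Katnal1) from a gene end. Without CTRL replicate 1 the calls at Agap1 (adjusted p = 0.0631), Irf8 (0.0589) and Lnpep (0.155) were lost, and DESeq2 did not call Rad50 (0.0574), Pla2g2d (0.550) or Lnpep (0.238). In the fit of all 8 libraries the Otud7a (0.0991) and Lnpep (0.0613) calls were lost. Without CTRL replicate 1 Otud7a was at 8.23 and Lnpep at -1.94, and without KO replicate 1 Pla2g2d was at -8.8 and Lnpep at -4.95. Fitted changes against a library at 0 depend on the prior count and are no bounds. With the replicate block 8598 peaks passed, 4368 higher and 4230 lower, including all 3875, whereas DESeq2 called 1579, glmTreat 641 and the fit of all 8 libraries 476 of the matched peaks.

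**Figure D1:**
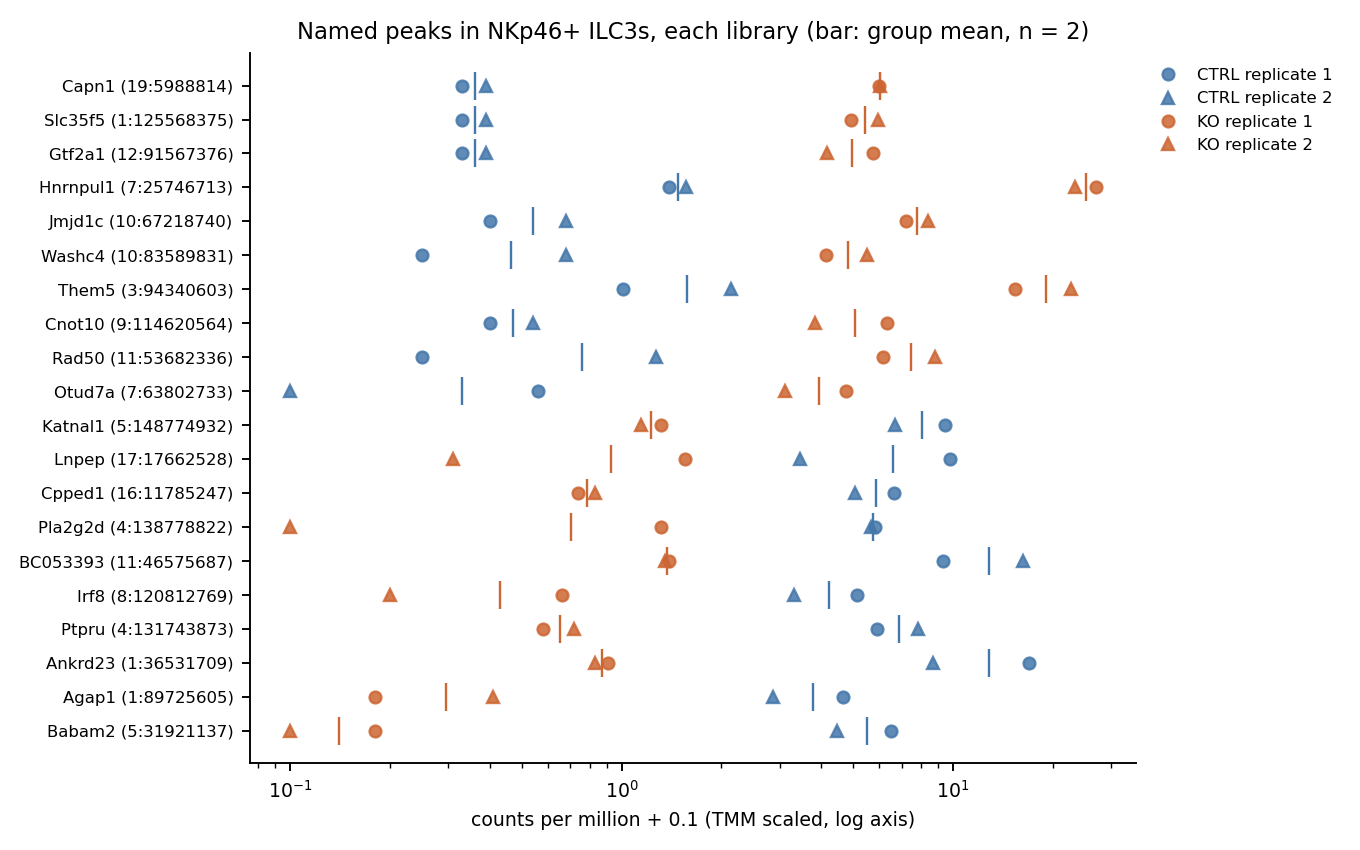
The 20 named peaks of NKp46+ ILC3s, with TMM-scaled CPM plus 0.1 on a log axis. Circles are replicate 1, triangles replicate 2, and vertical bars the mean of the 2 libraries of a group. CTRL (blue) and KO (orange) libraries do not overlap at any of the 20 peaks, as the rule that chose them required.

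Peaks around Rorc, which encodes the ILC3 lineage factor RORγt and whose promoter drives cre here, were more open in KO in both subsets. Summed over its peaks, Rorc rose from 288.81 ± 19.63 to 840.79 ± 57.59 CPM in NKp46+ cells (log2 1.54 ± 0.08, adjusted p = 2.9e-06). In NKp46- cells it went from 292.56 ± 62.54 to 773.96 ± 187.46 CPM (1.40 ± 0.22), which passed with the replicate block (adjusted p = 4.3e-36) and not without it (0.341). The blocked p leans on variance shared across genes, because few residual degrees of freedom remain in 4 libraries. The gain was not limited to Rorc. In NKp46+ cells 12 of 16 peaks between positions 94328467 and 94420619 of chromosome 3 rose, by 0.85 to 3.81, and this stretch also covers Them5, C2cd4d and Lingo4. The other 4 peaks in it did not, with log2 changes of -1.53 to -0.07. In NKp46- cells 17 of 22 peaks between 94320598 and 94420812 passed with the block, at 1.09 to 3.26 in that fit, and 0 without it (edgeR). In each subset 0 of the 3 peaks within 100 kb outside the stretch were raised. The ends were set at the outermost raised peaks within 100 kb of the Rorc peaks, so this count was fixed by definition. Every KO library carries cre and no CTRL library does. The transgene and the loss of Setd2 are therefore not separated, at this locus or at any other peak compared here.

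**Figure D2:**
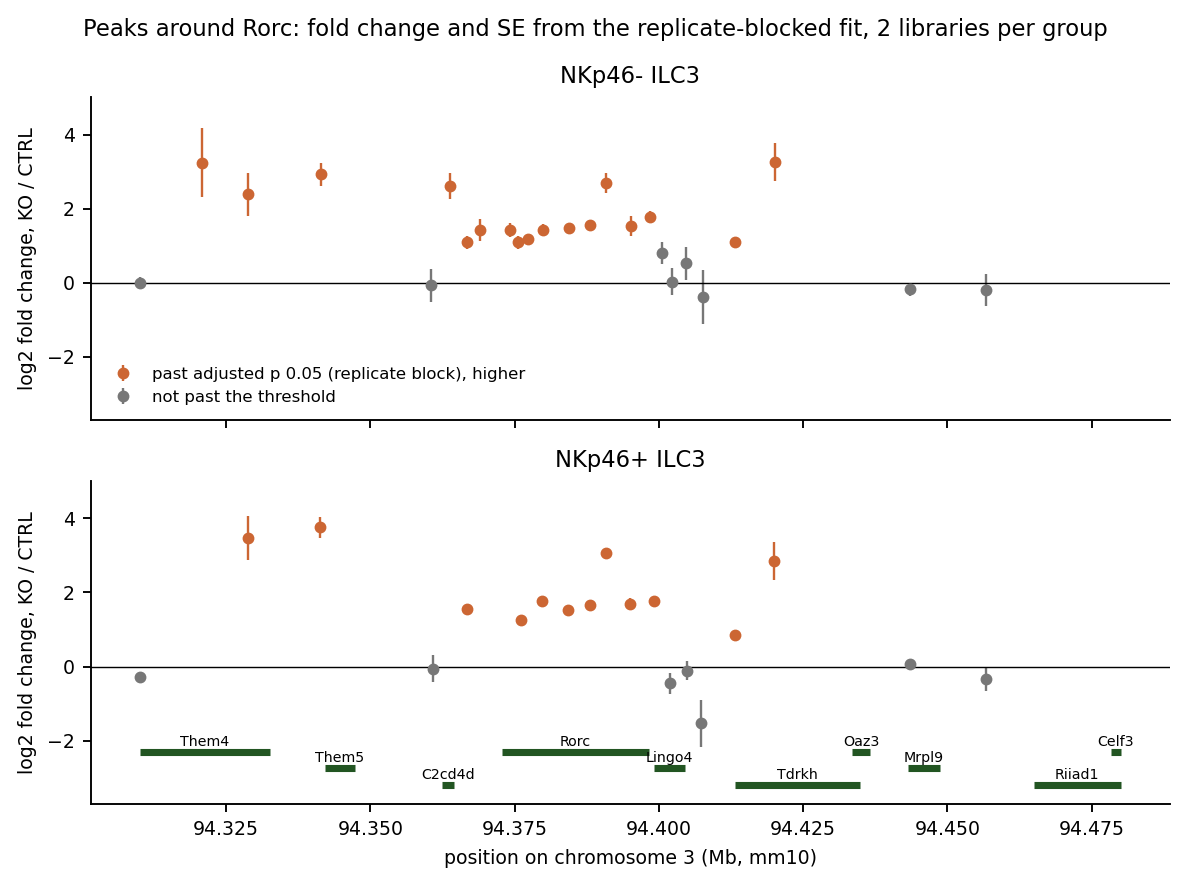
Log2 fold change (KO over CTRL) of each peak around Rorc by its position on chromosome 3 (Mb), from the fit with the replicate block, with SE bars and 2 libraries per group. Orange points passed an adjusted p of 0.05 upward, grey points did not, and green bars are genes. The 17 raised peaks in NKp46- and the 12 in NKp46+ cells end at nearly the same positions, with flat peaks on both sides.

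Setd2 itself kept an open gene end. Its peak at the gene end (chromosome 9, from 110531547) held 33.2 ± 1.75 CPM in CTRL and 33.0 ± 1.58 CPM in KO NKp46+ cells. Inside the gene, 2 weaker peaks gained: 110593310 to 110595215 by 1.68 ± 0.38 (adjusted p = 0.0094) and 110616840 to 110617764 by 2.24 ± 0.68 (0.046). Which exons are deleted is not stated, so these peaks do not measure the deletion. Among cytokine genes in NKp46+ cells, 1 peak near Csf2 (GM-CSF) fell by 1.03 (chromosome 11, 54223575 to 54224907, adjusted p = 0.0092), and 1 near Il17a fell by 1.09 (chromosome 1, 20725380 to 20726467, 0.036). With the replicate block 5 of 10 Csf2 peaks fell, and so did a peak at the end of Il17f (20783807 to 20784890, -0.68 ± 0.19, adjusted p = 0.0045, against 0.0513 without the block). At gene level Csf2 (-0.30 ± 0.09), Il17a (-0.44 ± 0.16) and Il17f (-0.27 ± 0.11) did not pass without the block (adjusted p = 0.0809, 0.121 and 0.172) and passed with it (3.0e-05, 0.012 and 0.049). Il22 (-0.09 ± 0.10), Ccr6 (-0.01 ± 0.12), Tbx21 (-0.19 ± 0.08) and Ncr1 (0.08 ± 0.10), which encodes NKp46, did not pass in either fit. A single Ncr1 peak rose by 0.78 (chromosome 7, 4341186 to 4342881, adjusted p = 0.030).

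Gains and losses in NKp46+ cells lay in different parts of the genome. Of the 2156 gains, 63.0% were in gene bodies, against 47.5% of tested peaks (odds ratio 1.93, 95% interval 1.77 to 2.12, Fisher exact p = 2.7e-49, adjusted 8.1e-49). Between genes lay 16.8% of gains and 31.1% of tested peaks (0.43, 0.39 to 0.49). Losses showed the opposite, with 44.2% between genes (1.79, 1.62 to 1.97) and 37.1% in gene bodies (0.64, 0.58 to 0.71). These intervals and p-values treat peaks as independent, which neighbouring peaks are not, and do not measure variation between mice. The genes with many gained peaks included Il23r, the IL-23 receptor of ILC3s, with 8 of 19 peaks, Stat1 with 5 of 7, Batf3 with 4 of 8, Stat3 with 4 of 9 and Itk with 4 of 9. Those with many lost peaks included Dscam, a cell adhesion gene, with 10 of 23 against 1 gained, Runx2 with 5 of 23 and Blk with 4 of 8. These examples were chosen after their values were seen.

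**Figure D3:**
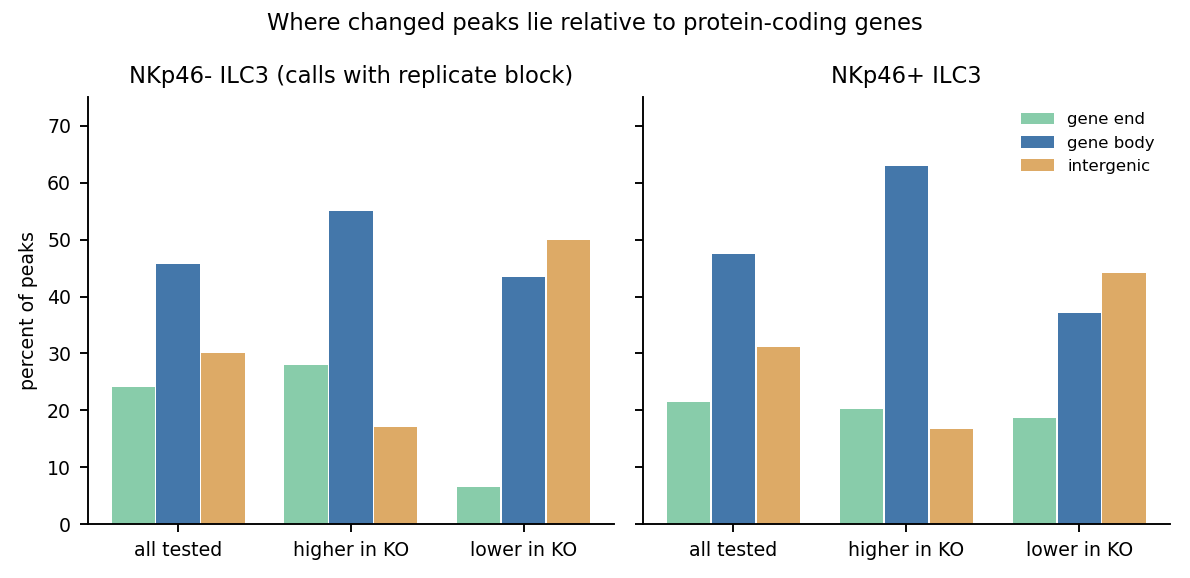
Percent of peaks at gene ends (green), in gene bodies (blue) and between genes (yellow) among all tested peaks and among peaks higher or lower in KO. NKp46- calls come from the fit with the replicate block. In NKp46+ cells 63.0% of gains and 37.1% of losses lay in gene bodies.

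Summed to genes, 954 of 14748 genes changed in NKp46+ cells, 562 upward and 392 downward, and 3056 with the replicate block. With peaks at gene ends alone 474 passed. Of 23 lists, 2 passed camera with the preset correlation, and 0 with an estimated one (adjusted p = 0.837 for both). The Notch signaling list shifted down (adjusted p = 0.030, median log2 -0.16). Of its 18 measured members 3 fell, Notch2 (-0.47 ± 0.09), the target genes Nrarp (-0.51 ± 0.14) and Dtx1 (-0.41 ± 0.08), 0 rose, and 8 fell when adjusted over the list alone. With the block 1 rose and 9 fell. The list of myeloid markers shifted up (adjusted p = 0.0095, median 0.29). Of 18 measured members 4 rose, Csf1r, the receptor of macrophage growth factor (4.49 to 14.09 CPM, 1.59 ± 0.26), Csf3r (1.19 ± 0.24), Cebpa (1.10 ± 0.29) and Mafb (1.09 ± 0.22), and 5 rose and 1 fell when adjusted over the list alone. With the block 6 rose and 1 fell. The Notch call was lost without CTRL replicate 2 (0.157) or KO replicate 2 (0.0568) and with gene ends alone (0.117). Without KO replicate 2 the myeloid call was lost as well (0.0513). Fry, which asks whether a list moves 1 way on balance, called 0 lists at 0.05 (smallest adjusted p = 0.112).

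The remaining lists of NKp46+ cells did not pass camera (adjusted p = 0.0606 to 0.904), though with the replicate block MHC class II presentation and interferon response shifted up (both 0.0332). Neither passed with an estimated correlation (adjusted p = 0.837 for both, and 0.891 with the block). Of 15 MHC class II members 1 rose, Cd74, the invariant chain (54.66 to 100.29 CPM, 0.86 ± 0.12), with 5 when adjusted over the list alone and 5 with the block. Of 29 interferon response members 1 rose, Ifit3 (0.88 ± 0.21), and 1 when adjusted over the list alone, while 10 rose and 1 fell with the block. These moved alongside the myeloid markers above.

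Among genes of ILC3 function in NKp46+ cells, 2 of 24 ILC3 identity members rose, Rorc and Il23r (0.40 ± 0.08), and 2 when adjusted over the list alone. Here the median was -0.03 with a mean of 0.04 and a camera direction of up. Of 24 CCR6+ ILC3 members 2 rose, Cd74 and Gpr183 (0.33 ± 0.09), with 6 up and 2 down adjusted over the list alone. Of 33 members of the NKp46+ and type 1 list 3 rose: Il12rb2, an IL-12 receptor chain (1.53 ± 0.17), Il18rap (0.54 ± 0.09) and the granzyme Gzma (0.98 ± 0.19), with 5 adjusted over the list alone. Hpgds rose (0.42 ± 0.11) in the list of 15 ILC2 and type 2 genes, where 1 rose and 1 fell adjusted over the list alone. Of 22 effector cytokines Il1b rose (1.18 ± 0.27). Adjusted over the list alone, 4 rose and 7 fell. Of 26 chemokine receptor and adhesion genes Cxcr4 (0.44 ± 0.09) and Gpr183 rose and S1pr4 fell (-0.37 ± 0.10), with 3 up and 1 down adjusted over the list alone. Of 14 inhibitory receptors Ctla4 fell (-0.43 ± 0.09). Adjusted over the list alone, 1 rose and 2 fell (median -0.09, mean 0.04). With the block 6 rose and 5 fell in ILC3 identity, 7 and 5 in CCR6+ ILC3, 6 and 2 in the type 1 list, 2 and 2 in ILC2 and type 2, 4 and 9 among effector cytokines, 3 and 2 among chemokine receptors and 2 and 3 among inhibitory receptors.

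For signaling and growth in NKp46+ cells, Batf3 (0.56 ± 0.11) and Nr4a2 (0.40 ± 0.10) rose and Fosl2 (-0.44 ± 0.08) and Myc (-0.38 ± 0.09) fell among 30 AP-1 and activation genes, with 3 up and 2 down adjusted over the list alone. Acvr2a, an activin receptor, fell (-0.57 ± 0.10) among 19 TGF-beta genes, with 1 up and 2 down adjusted over the list alone. Among 11 AhR targets Notch2 and Nqo1 (-0.96 ± 0.22) fell, and these 2 did when adjusted over the list alone. The cell cycle genes E2f7 (-0.70 ± 0.12), Ccne1 (-0.43 ± 0.08) and the inhibitor Cdkn2c (-0.46 ± 0.09) fell among 32, and 3 did when adjusted over the list alone. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose from 21.49 to 57.11 CPM (1.40 ± 0.13) among 23 apoptosis genes, with 2 up adjusted over the list alone. Gapdh rose (0.47 ± 0.09) among 23 glycolysis genes, with 1 up and 1 down adjusted over the list alone. Smyd2 fell (-0.32 ± 0.09, adjusted p = 0.049) among 27 histone enzymes, with 0 adjusted over the list alone. With the block 10 rose and 4 fell among AP-1 genes, 3 and 6 among TGF-beta genes, 1 and 4 among AhR targets, 4 and 3 in cell cycle, 6 and 1 in apoptosis, 3 and 2 in glycolysis and 3 and 2 among histone enzymes.

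Markers of other cell types moved unevenly in NKp46+ cells. Of 12 B and plasma cell genes Ebf1 rose (1.08 ± 0.25) and Blk fell (-0.89 ± 0.10), also when adjusted over the list alone, where the median was -0.05 and the mean 0.02. Of 11 epithelial genes Lgr5 rose (0.84 ± 0.17), as it did adjusted over the list alone. Of 11 stromal and endothelial genes Cdh5 rose (0.98 ± 0.24), with 2 up adjusted over the list alone. With the block 1 rose and 3 fell among B and plasma cell genes, 3 and 1 among epithelial genes and 3 and 2 among stromal and endothelial genes. None of 10 T cell or 5 mast cell and basophil genes passed in the edgeR test, over all genes, adjusted over the list alone or with the replicate block. Their smallest gene-level adjusted p was 0.274 and 0.295, at Cd6 and Hdc.

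**Figure D4:**
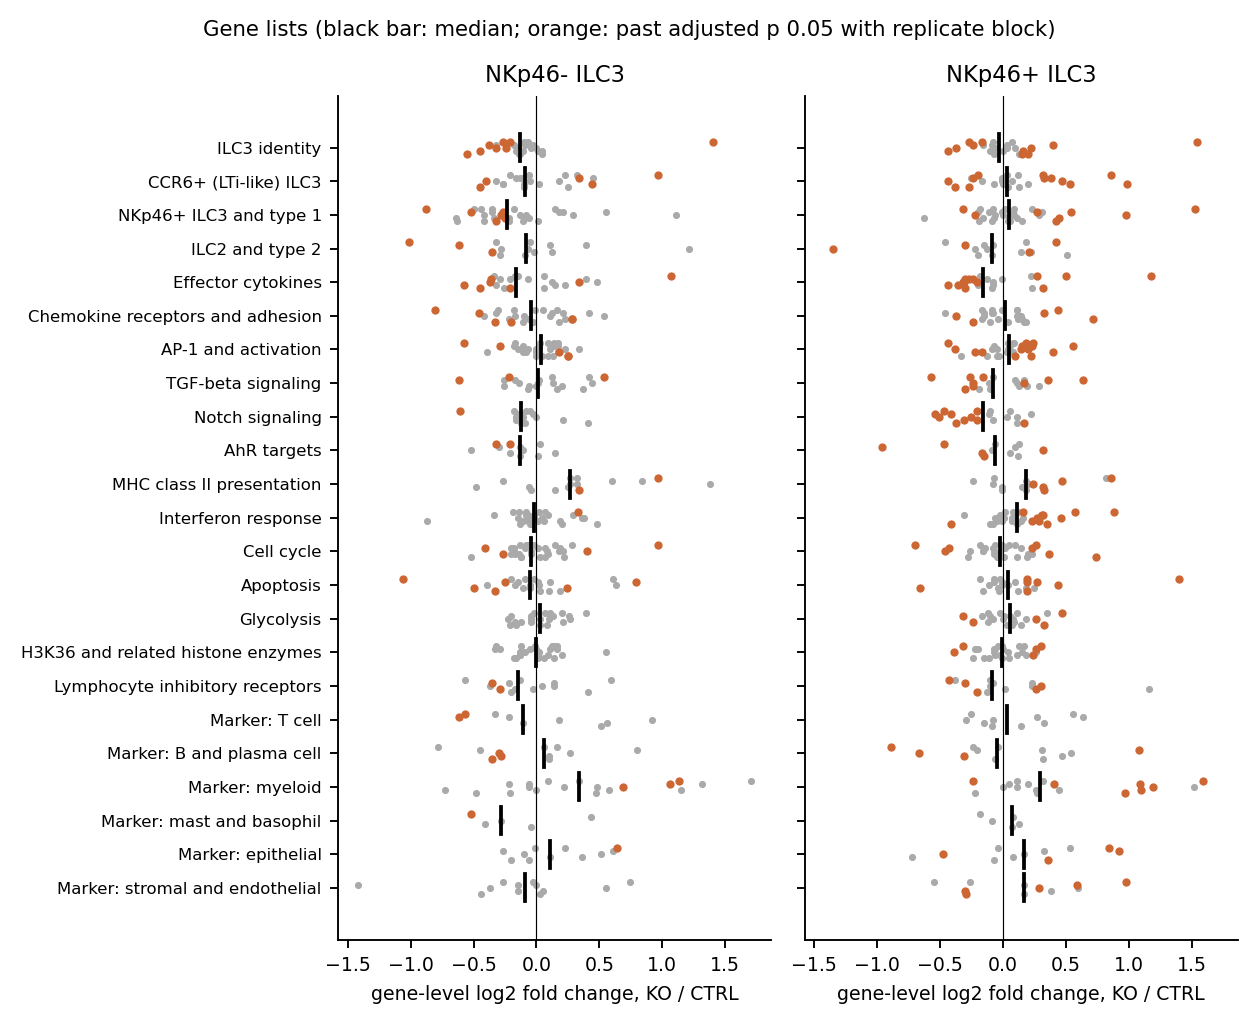
Gene-level log2 fold change (KO over CTRL, from the fit without block) of every measured member of the 23 lists, 1 point per gene, in NKp46- (left) and NKp46+ cells (right), with 2 libraries per group. Black bars are list medians, and orange points passed an adjusted p of 0.05 with the replicate block. The myeloid marker medians were 0.34 and 0.29, the Notch medians -0.12 and -0.16.

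The second comparison asked the same of NKp46- ILC3s. Without the replicate block 1 of 46235 peaks passed, inside Hnrnpul1 (chromosome 7, 25744589 to 25745423). It rose from 0.97 ± 0.19 to 20.1 ± 2.49 CPM (log2 4.30 ± 0.42, n = 2 per group, adjusted p = 0.037), with 3775 peaks at an unadjusted p under 0.05. With the block 1779 peaks passed, 975 more open and 804 less open in KO. Of these, the largest named gains after Hnrnpul1 (blocked adjusted p = 4.9e-14) were at Cnot10 (3.00 ± 0.64), Rorb, a nuclear receptor related to Rorc (2.98 ± 0.50), Them5 (2.93 ± 0.31), Pnpla7, Clec2d, a ligand of NK receptors (2.84 ± 0.56), Noc4l, Psma1, Nisch and the Notch ligand gene Dll1 (2.77 ± 0.50). The largest named losses were assigned to Fhit (-3.25 ± 0.66), Nek2 (-3.16 ± 0.57), Ackr2, a decoy chemokine receptor (-3.09 ± 0.41), Sntb1, Mitf, a transcription factor of mast cells and melanocytes (-2.70 ± 0.50), Unc5c, Ints6, Ier5, Chil1 and Gadd45g (-2.42 ± 0.65). The peaks of Nek2, Ackr2, Ints6, Ier5, Chil1 and Gadd45g lay between genes, 1516 bp (Ackr2) to 55954 bp (Ier5) from a gene end. None of these passed in the unblocked edgeR fit that gave the 1 call (adjusted p = 0.0889 to 0.459), but other unblocked settings called some. DESeq2 called Them5 (adjusted p = 0.00012) and Ackr2 (0.0048). With edgeR, the fit of all 8 libraries called Them5 (0.0078), Nek2 (0.0131) and Rorb (0.0436), among others. Leaving out the count filter gave Rorb at 0.00017, among others. KO replicate 2 held 0 counts at Mitf, Sntb1 and Ier5, whose estimates without KO replicate 1 were -8.73, -7.99 and -7.92, and Clec2d was at 4.13 without CTRL replicate 1. DESeq2 with the block did not call Ier5 (adjusted p = 0.758). The single call was lost with total counts (0.0532), with a mean count of at least 20 (0.0855), with limma-voom (0.225) and with glmTreat (0.0539). DESeq2 called 30 peaks, 147 with the block, leaving out the filter gave 328, the fit of all 8 libraries 112, and leaving out 1 library 100 (KO replicate 2) to 190 (CTRL replicate 1), with 142 without CTRL replicate 2 and 173 without KO replicate 1.

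With the block, 55.0% of NKp46- gains lay in gene bodies (odds ratio 1.45, 95% interval 1.28 to 1.66, Fisher exact p = 8.2e-09), though with gene ends of 3 kb the odds ratio was 1.13 (0.99 to 1.29, p = 0.0554). Between genes lay 49.9% of losses (2.35, 2.04 to 2.71), while gene bodies held 43.5% of them (0.91, 0.79 to 1.05, Fisher exact p = 0.199), where NKp46+ losses had an odds ratio of 0.64. Gene ends held 6.59% of losses and 24.1% of tested peaks (0.22, 0.16 to 0.29), against an odds ratio of 0.84 for NKp46+ losses, or 1.22 with the block. The 1 call without the block gives no share. Among genes with several changed peaks, Rorc had 10 of 10 and Cd74 3 of 3 more open, and Khdrbs3 had 8 of 8, Dscam 7 of 21 and Slc8a1 5 of 13 less open, examples chosen after their values were seen.

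Summed to genes, 0 of 14479 passed in NKp46- cells with edgeR (803 at an unadjusted p under 0.05), and 1106 with the block, 466 up and 640 down. Leaving out 1 library gave 15 (KO replicate 2) to 58 (CTRL replicate 2) genes, with 57 without CTRL replicate 1 and 41 without KO replicate 1. The fixed genes with the block were Rorc (above), Csf2 (-0.37 ± 0.08, adjusted p = 0.000456), Il17a (-0.46 ± 0.15, 0.049) and Il22 (-0.23 ± 0.08, 0.048), while Il17f (-0.32 ± 0.14, 0.148), Tbx21 (-0.50 ± 0.23, 0.188), Ncr1 (-0.64 ± 0.39, 0.370), Ccr6 (0.18 ± 0.09, 0.265) and Setd2 (0.16 ± 0.15, 0.599) did not pass. Inside Tbx21 a single peak (chromosome 11, 97112410 to 97113352) was lower with the block (-1.378 ± 0.415, adjusted p = 0.0386) and not called without it (0.413). Without CTRL replicate 1 or KO replicate 2 the unblocked Il22 estimate changed from -0.21 to 0.01 or 0.09.

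Of the 23 lists, 3 passed camera in NKp46- cells with the preset correlation, and 0 with an estimated one (adjusted p = 0.974 for these 3). The NKp46+ and type 1 list shifted down (adjusted p = 0.0078, median -0.23, 7 members positive and 23 negative). With the block 6 of its 30 measured members fell, among them Itga1 (-0.88 ± 0.17 without the block) and the chemokine gene Xcl1 (-0.52 ± 0.17), and 0 rose. The MHC class II list shifted up (0.0078, median 0.27), with Cd74 (133.3 to 261.75 CPM, 0.97 ± 0.24) and H2-Ab1 (0.34 ± 0.16) among 2 of 15 that rose with the block. Myeloid markers shifted up (0.0088, median 0.34, 13 positive and 6 negative), and Mafb (13.29 to 29.5 CPM, 1.13 ± 0.30), Cebpa (1.06 ± 0.30) and Mertk (0.69 ± 0.26) were the 3 of 19 that rose with the block. With the block ILC3 identity (0.0053) and AhR targets (0.045) also shifted down (0.818 for both with an estimated correlation), but ILC3 identity turned up without CTRL replicate 1 (0.4925) or KO replicate 2 (0.3009). Fry called 0 lists (smallest adjusted p = 0.828). The type 1 call was lost without CTRL replicate 1 (0.802) or KO replicate 2 (0.878), the library that stood apart, the MHC class II call without CTRL replicate 2 (0.442) or KO replicate 1 (0.178), and the myeloid call without CTRL replicate 2 (0.395) or KO replicate 2 (0.0847).

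Without the block 0 members of any list passed over all genes in NKp46- cells (edgeR). Adjusted over the list alone, Rorc rose in ILC3 identity and Itga1 fell in the type 1 list, and 0 passed in the other 21 lists. With the block the counts were 1 up and 7 down of 24 for ILC3 identity, with Nfil3 (-0.38 ± 0.16) and Ahr (-0.32 ± 0.15) lower, and 0 up and 2 down of 11 AhR targets. They were 3 up and 2 down of 24 for CCR6+ ILC3 (median -0.09, mean 0.02), with Tnfrsf11a up and Nrp1 down, 0 up and 3 down of 14 for ILC2 and type 2, with Il1rl1, the IL-33 receptor (-1.01 ± 0.33), and Bcl11b (-0.62 ± 0.21), and 2 up and 5 down of 22 effector cytokines, with Il1b up (1.07 ± 0.40) and Il6 down (-0.58 ± 0.30). Chemokine receptors had 2 up and 4 down of 26, with the gut-homing receptor Ccr9 down (-0.81 ± 0.28), and inhibitory receptors 0 up and 2 down of 14, Klrg1 and Tigit. The AP-1 list had 3 up and 2 down of 30, with Myc down (-0.58 ± 0.20), TGF-beta 1 up and 2 down of 19, with Smad6 up and Acvr2a down (-0.62 ± 0.23), and Notch 0 up and 1 down of 18, Dtx1 (-0.61 ± 0.17). Interferon response had 1 up of 29, Stat1 (0.33 ± 0.15), cell cycle 2 up and 2 down of 32, with Ccnd1 up (0.97 ± 0.33), and apoptosis 2 up and 4 down of 23, with Pmaip1 up (0.79 ± 0.21) and Bcl2a1d down (-1.06 ± 0.28). Glycolysis (23 genes) and histone enzymes (27) had 0. Among markers, T cells had 2 down of 9, Cd3d and Bcl11b (median -0.11, mean 0.03), B and plasma cells 3 down of 11, with Blk and Prdm1 (median 0.06, mean -0.06), mast cells and basophils 1 down of 5, Hdc, epithelial cells 1 up of 11, Lgr5, and stromal and endothelial cells 0 of 12.

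The next comparison asked whether the genotype effect differs between the subsets. Across 37074 matched peaks outside the Rorc stretch, log2 fold changes of the subsets correlated at Pearson r = 0.59 and Spearman rho = 0.49. That is across peaks, which are not independent replicates, and the subsets share no library. Of 1538 matched peaks that rose in NKp46+ cells, 1469 (95.5%) had a positive change in NKp46- cells, against 50.6% of all matched peaks. Of 1399 that fell, 1161 (83.0%) had a negative change, against 49.4%. Tested as sets in NKp46- libraries, the NKp46+ gains shifted up (fry p = 0.016, camera with estimated correlation p = 0.020) and the losses down (0.0072 and 0.0011). These set tests were chosen after the data were seen. Between NKp46+ calls and blocked NKp46- calls, 457 gains were shared where independent lists would share 33.1, and 333 losses where they would share 27.0. The direct test of the difference found 0 of 38025 matched peaks with edgeR (1074 at an unadjusted p under 0.05) and 0 with DESeq2 (605). With the replicate block 146 passed, 36 with a more positive and 110 with a more negative effect in NKp46+ cells. Examples were Gadd45a, where a peak between genes went from 11.23 to 2.46 CPM in NKp46- and from 28.17 to 25.33 CPM in NKp46+ cells, and Satb1, Ankrd23 and Pnpla7 in the other direction.

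**Figure D5:**
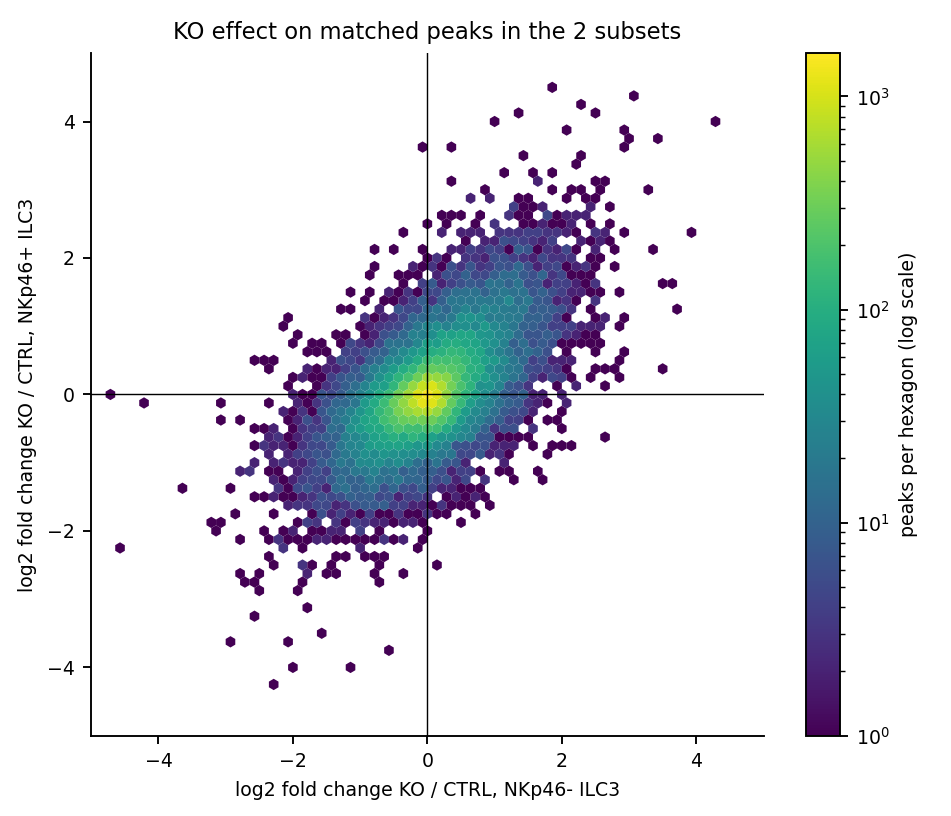
Log2 fold change (KO over CTRL) of 37086 matched peaks in NKp46- (horizontal) and NKp46+ cells (vertical), without block, where color is the number of peaks per hexagon on a log scale. The peaks around Rorc are included, and 2 peaks lie outside the plotted range. The changes correlated at r = 0.59 with the Rorc stretch left out.

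The last comparison set CTRL NKp46+ against CTRL NKp46- cells, whose labels share no date-like code. Each subset was counted over its own peak intervals, so a difference here can come from the intervals as well as from accessibility. Of 38025 matched peaks, 809 had higher and 1029 lower counts in NKp46+ cells (1838 in all, edgeR). The log2 differences followed the log2 ratio of the 2 widths (Spearman rho = 0.41). With counts per width 835 passed, 682 of the 1838 among them, and of 12140 pairs that overlap by at least 90%, 194 passed. The peak at the end of Ncr1, the gene of the sorting marker (chromosome 7, 4337252 to 4338493), held 67.03 ± 2.11 CPM in NKp46+ and 10.6 ± 0.16 CPM in NKp46- cells (log2 2.66 ± 0.20, adjusted p = 0.00017, and 2.02 ± 0.20 per width). Tbx21, which encodes T-bet of type 1 lymphocytes, was higher in NKp46+ cells at 2 peaks (1.81 ± 0.25 and 1.05 ± 0.23, or 1.25 and 1.49 per width), and so was a peak near Csf2 (1.40 ± 0.25, or 1.05 per width). A peak near Ccr6, a receptor of LTi-like ILC3s, was lower (-1.41 ± 0.23, or -1.13 per width). A peak at the end of Setd2 was lower as well (-2.72 ± 0.54, adjusted p = 0.013, or -2.67 and 0.0252 per width), but its intervals of 875 bp in NKp46- and 924 bp in NKp46+ cells share only 485 bp. Near Il22 a peak at -0.90 ± 0.22 (adjusted p = 0.037) was at 0.03 per width (0.973), so that call goes with its interval, 2498 bp in NKp46- and 1443 bp in NKp46+ cells. The other large differences were higher at Gpr55 (2.74 ± 0.48), Chd7, Stard7 and Ikzf2, the gene of Helios (2.44 ± 0.33), and lower at Otud7a (-4.41 ± 0.98), Fermt2, Dnajc6, Klhl29 (-4.13 ± 0.34) and Cpn1. Per width Otud7a (adjusted p = 0.0795) and Fermt2 (0.0560) did not pass. Without either CTRL NKp46+ library 125 or 126 peaks passed, without KO NKp46+ replicate 1 or 2 it was 1016 or 1045, and matching by any overlap gave 3359. Gpr55 (adjusted p = 0.0504 and 0.0823), Chd7 (0.0738 and 0.0630) and Fermt2 (0.0601 and 0.0911) did not pass without CTRL NKp46+ replicate 1 or 2. Otud7a did not pass without either of these (0.117 and 0.178), without CTRL NKp46- replicate 1 (0.365) or without KO NKp46+ replicate 1 (0.0501). Without CTRL NKp46- replicate 1 Gpr55 was at 4.33, and without CTRL NKp46+ replicate 1 Otud7a, Fermt2 and Dnajc6 were at -8.58, -8.12 and -9.03.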

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

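Which peaks to name from the blocked test of the difference of KO effects was decided only after its count was seen.

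The KO effect differed between the subsets at 146 of 38025 matched peaks with the replicate block, and at 0 without it, where every peak named here had an adjusted p of 0.9999. The fit with the block has 2 residual degrees of freedom and the fit without it 4. A more positive effect in NKp46+ cells was found at Bcl11b (7.58), Snx18 (4.50), Kcnh6 (2.55), Adra1b (1.91) and Gadd45a (1.81), and a more negative one at Ankrd23 (-2.88), Pnpla7 (-2.58), Satb1 (-1.62), Ap1b1 (-1.60) and Rdh13 (-1.58), all as log2 differences.

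The Bcl11b value rests on 63 counts in CTRL and 0 in KO NKp46- libraries, which is at least 14.5-fold lower at a floor of 3 counts over the group, while the exact two-sided 95% interval, which does not use the floor, starts at 11.5. At Snx18 the counts were 40 and 1, a 27.6-fold loss with an exact interval of 4.68 to 1120. The floor and both intervals cover counting error only, and replicates varied by more than that. Bcl11b encodes a transcription factor that T cells and ILC2s depend on, and its peak held 3.80 and 2.40 CPM in CTRL and KO NKp46+ cells. A run of 6 other peaks at Bcl11b fell in NKp46+ cells with the block (log2 -1.63 to -0.89). The difference therefore rests on the named low-count peak and does not mean that Bcl11b closed only in NKp46- cells. The loss at Ankrd23 was larger in NKp46+ cells (13.62 to 0.83 CPM) than in NKp46- cells (6.29 to 2.91 CPM), and Pnpla7 opened only in NKp46- cells (1.37 to 9.42 CPM against 6.30 to 7.48 CPM).

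For Kcnh6, Ap1b1, Rdh13, Satb1, Snx18 and Gadd45a the NKp46- replicates of CTRL or KO differed by nearly as much as their mean or by more, such as 25.03 ± 23.30 CPM for Kcnh6 in CTRL and 2.46 ± 2.01 CPM for Gadd45a, a stress-response gene, in KO. For these 6 the difference without the block moved by over 1.5 times when 1 library was left out.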

How the results depend on the processing

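The tests with the replicate block and loess offsets or DESeq2 were chosen only after the pairing of replicates was seen, and those with counts per width or 90% overlap only after the subset contrast was seen.

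For KO against CTRL peaks in NKp46- cells, 1 call became 1779 with the replicate block, 1665 with the replicate block and loess offsets, and 147 with the replicate block and DESeq2. It became 30 with DESeq2, 328 with no count filter, 3 at an adjusted p of 0.1 and 112 in the fit of all 8 libraries. It became 0 with total counts, with a mean count of at least 20, with limma-voom and with glmTreat. These held 3600, 2748, 3602 and 2023 peaks at an unadjusted p under 0.05. Leaving out 1 library gave 100 to 190. The single library then left in a group is assumed to vary like the other groups.

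In NKp46+ cells, 3875 peaks became 8598 with the replicate block, 7028 with block and loess offsets, 861 with block and DESeq2, 1579 with DESeq2, 6254 at an adjusted p of 0.1, 641 with glmTreat and 476 in the fit of all 8 libraries. Size factors, total counts, loess offsets, filters, limma-voom and omission of chromosomes X and Y moved it by less than 1.5 times. Omission of 1 library left a number of calls of similar size, but many of the 3875 peaks did not pass again. The shares in gene bodies and between genes kept their direction with the replicate block and with a gene end of 3 kb. The share at gene ends did not: the odds ratio of lower peaks went from 0.84 to 1.22 with the block, and that of higher peaks from 0.93 to 1.13 with 3 kb.

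For the difference of KO effects, 0 became 146 with the replicate block and stayed 0 in every other setting. The subset contrast of 1838 peaks became 3359 with matching by any overlap, 194 with matching by 90% overlap and 835 with counts per width, and ranged from 125 to 2407 when 1 library was left out.

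At gene level, 0 genes in NKp46- cells became 1106 with the replicate block, 2 with no count filter and 15 to 58 without 1 library. In NKp46+ cells 954 became 474 with peaks at gene ends alone and 3056 with the replicate block. The 3 lists called in NKp46- cells became 5 with the replicate block, 2 to 7 without 1 library and 0 with an estimated correlation. The 2 lists called in NKp46+ cells became 4 with gene ends alone, 4 with the replicate block, 0 to 4 without 1 library and 0 with an estimated correlation.

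Small estimates changed sign. Setd2 in NKp46- cells ranged from -0.12 to 0.43 without 1 library (-0.02 without KO replicate 2), Il22 from -0.62 to 0.09 (0.01 without CTRL replicate 1) and Ccr6 from -0.03 to 0.44 (-0.01 without KO replicate 1). In NKp46+ cells Il22 ranged from -0.21 to 0.04 (0.02 without KO replicate 2) and Ccr6 from -0.12 to 0.12 (0.09 without KO replicate 1), Ccr6 was 0.00 with total counts, and Ncr1 was -0.06 with gene ends alone. The ILC3 identity list in NKp46- cells turned from down to up without CTRL replicate 1 (adjusted p = 0.4925) and without KO replicate 2 (0.3009), and stayed down, at 1.159e-05, without CTRL replicate 2.

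Motif content and the correction for GC share, alone or with the block, were not run because the genome sequence was not used here.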

Other observations

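The tests of runs of neighbouring peaks, the second myeloid list, the Rorc stretch and the classes of abundance were all chosen only after the results they bear on were seen.

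A small part of the changed peaks lay in runs of neighbours, though more of them than chance gave. In NKp46+ cells 22 runs of at least 4 neighbouring peaks changed the same way (12 up, 10 down), where shuffling the calls over 1000 rounds gave 0.23 on average and 2 at most. With the replicate block 105 did (52 up, 53 down), where shuffling gave 4.59 and 12, and the longest was 9 peaks at Hip1r and Vps37b. Without the block, after Rorc with 8, the longest runs were 6 lower peaks at Dscam (log2 -2.65 to -1.11) and 6 lower peaks on chromosome 18 with no gene near. Stat1, a signaling factor of interferon responses, had 5 higher peaks (1.84 to 2.64), Itk, a kinase of lymphocyte receptor signaling, 4 (0.89 to 2.85), and Blk 4 lower peaks (-2.12 to -0.51).

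In NKp46- cells 5 such runs passed with the replicate block, where shuffling gave 0.021 on average and 1 at most. Rorc had 12 peaks, Khdrbs3 8 lower peaks (-2.82 to -1.42, chromosome 15, 68927712 to 69108876), Prkca and Deup1 4 lower peaks each, and Cd74 with Tcof1 4 higher peaks (0.67 to 1.30). Deup1 also had 4 lower peaks in NKp46+ cells (-1.30 to -0.78), so this run was shared by cells that share no library.

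The stretch of raised peaks around Rorc ended at nearly the same positions in both subsets, next to peaks that did not change. Extra copies of the region carried with cre, such as a large transgene, might raise all peaks alike. The values argued against that, because the changes differed between peaks (Cochran Q, chi-square p = 4.548e-20 in the subset where it was larger). In NKp46+ cells 4 of 16 peaks did not rise. The Q test used SEs of the blocked fits, which lean on variance shared across peaks. Copies with an accessibility of their own would raise peaks unevenly and stop at the ends of the insert. The 0 raised peaks within 100 kb outside do not test this, because the outermost raised peaks set the ends of the stretch. A change at the native locus after loss of Setd2 could raise the same 12 peaks. These last explanations cannot be told apart without a control that carries cre alone, and the predictions for all 3 were written after the values were seen.

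Gains inside genes and losses between genes could come from a trend with abundance, but the odds ratio for gene bodies among gains was 1.83 (95% interval 1.67 to 2) within 6 classes of abundance, which argued against it. KO libraries had a higher share of counts in the weakest of 3 classes of peaks (3.53% and 3.57%, against 3.2% and 3.0%), and the median log2 change fell from 0.19 in the weakest of the 6 classes to -0.04 in the strongest, so more background reads may add to gains of weak peaks. Spread evenly, they would raise these at all locations alike. In the weakest of 3 classes of peaks the median log2 change was 0.37 at gene ends, 0.2 in gene bodies and 0.05 between genes. The excess of 0.15 in gene bodies over peaks between genes argued against an evenly spread background as its source. Gene ends rose most, so this rise was not particular to gene bodies, and whether background falls evenly was not tested. Setd2 marks the bodies of transcribed genes, and loss of that mark might open sites within them. Peaks in bodies of genes with a strongly open end gained more often (6.95% against 4.97%, pooled odds ratio 1.42, 1.26 to 1.6), short of the 1.5 set beforehand for that test. An open end is a rough stand-in for transcription and GC share was not tested, so this remains open.

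Myeloid cells among the sorted KO cells may explain the rise of myeloid markers. A second list of myeloid genes lay at percentile 100 of 10000 random lists of like abundance in both subsets, with 34 of 43 members positive in NKp46+ and 35 of 42 in NKp46- cells. C1qa (1.35 ± 0.28), Tlr2 (1.32 ± 0.25) and Msr1 (1.91 ± 0.46) rose in NKp46+ cells. A rise of weakly open genes in general was argued against by percentile 98.6 for the first list. Myeloid genes that are well open in both genotypes, which a few foreign cells would barely move, went both ways in NKp46+ cells. Il1rn fell (57.95 to 36.21 CPM, -0.67 ± 0.15, edgeR adjusted p = 0.021). Spi1 (0.11), Cd14 (-0.22), Fcgr1 (79.56 to 79.33 CPM) and Irf8 (-0.09) did not rise. Csf2ra did (174.68 to 241.17 CPM, 0.47 ± 0.08, edgeR adjusted p = 0.0048), and with the block so did Cd300a (61.75 to 78.49 CPM) and Fcgr4 (81.59 to 99.68 CPM). Opening of myeloid loci within ILC3s could also give the 17 second-list genes that rose with the block. So the presence of myeloid cells met its prediction, but opening within the ILC3s could meet it as well. The second list does not tell these explanations apart, because bulk counts do not say which cell a read came from. The markers of the sort gate are not stated either.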
